A study of Mus musculus with 4 samples.

How the data were processed

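The values analysed are UMI counts per gene and cell. Per the submitters' processing notes, the authors made these counts with Cell Ranger 6.1.2 and the mm10 reference, and they were deposited as filtered matrices of barcodes by 32285 features. Per the labels' protocols, ears or 2 mm punches were digested for 1 hour with Liberase TL, live cells were sorted without a gate on cell type, libraries were made with 10x Genomics 3' v3 chemistry for a target of 10000 cells, and sequencing ran on a NextSeq 2000. Whether intronic reads were counted, how cells were called and which annotation release was used are not given in the sources used here. The lowest UMI count per barcode was 500, 501, 502 and 500 in whole ear 1, whole ear 2, the niche and the non-niche library. The labels give 1 replicate of niche and of non-niche and 2 of whole ear, and they do not say whether the whole ears were immunized or came from separate animals. All 4 libraries carried Xist at 509 to 627 CPM (counts scaled to a common total), and the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had at most 3 UMIs in any library, so all came from female mice.

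Cells with fewer than 200 detected genes or more than 15% mitochondrial UMIs were left out: 259 and 476 in whole ear 1, 363 and 354 in whole ear 2, 383 and 194 in the niche and 543 and 378 in the non-niche library. Doublet scores came from Scrublet as run by scanpy 1.11.5. Its automatic threshold marked 304, 37, 0 and 1 cells in whole ear 1, whole ear 2, niche and non-niche, so the highest scores were removed instead at 0.8% per 1000 cells recovered: 622, 106, 110 and 114 cells. That left 19008 cells. The doublet rule was chosen after the scores were seen.

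The 4 libraries were clustered together: 2000 variable genes, 40 principal components, 15 neighbours and Leiden clustering at resolution 1, without batch correction, since the labels tie no library to a batch. The members of 15 response lists were left out of the clustering genes so that the compared responses did not shape the classes. A cluster took the class with the largest part of its fixed markers among the first 100 genes of the cluster, ranked by level over the median cluster. Thresholds for this were set after seeing the data: genes ranked were detected in at least 25% of the cells of the cluster, at least 3 markers were needed, no other class could have more markers among the top 10 genes, and no more than 1 of the top 3 genes could be a marker of another class. This gave 33 clusters, of which 2 stayed unnamed, cluster 3 (leading genes Hba-a1, Hbb-bt, Hbb-bs, Apod, Dcn) and cluster 18 (Ctla2a, Hlf, Gata3, Areg). Neutrophil-like cells were those of clusters 7, 8, 9, 10 and 15, monocyte-like those of 11 and 12 (Lyz2, Chil3), macrophage-like those of 13 (C1qb, Aif1, C1qa) and 17 (Nos2, Arg1, Spp1), dendritic cell-like those of 19 (H2-Aa, Ccr7, Fscn1), T cell-like those of 5, 6, 16 (Trdc, Cxcr6) and 28 (Cd3g, Trdc, Areg), and fibroblast-like those of 0, 1, 2, 21 and 30. Genes that define a cluster are no results.

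Each class with at least 50 cells in both the niche and the non-niche library was compared: 5 classes. Counts were summed per library and class, scaled by the class total to CPM. The log2 ratio of niche to non-niche had 0.5 counts added to each sum, and its 95% interval came from the exact binomial distribution of 1 sum given both. Shares carry exact binomial and sums in CPM exact Poisson intervals. Where 1 sum was 0, the ratio is given as at least the value reached with 3 counts. The size counted was an absolute log2 ratio of at least 1 among genes with at least 100 UMIs in both libraries together. A TMM scaling by edgeR 4.0.16 was run as an alternative and added 0.29 to every log2 ratio in neutrophil-like, 0.20 in monocyte/macrophage-like, 0.07 in dendritic cell-like and 0.06 in T cell-like cells, and −0.06 in fibroblast-like cells.

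Genes were named by a rule. In each class these were the 5 highest and 5 lowest log2 ratios among genes past the size whose absolute log2 ratio also exceeded that between the whole ears. Mitochondrial, ribosomal, predicted, sex-linked, haemoglobin, immunoglobulin and T cell receptor genes and markers of other classes were left out of these. Of each gene list, up to 4 members with the largest absolute log2 ratio and at least 50 UMIs were named, and Cxcl9, Cxcl10 and Ifng always. The text prints a part of the genes so named, and the totals of values under other settings leave out 2 that are not reported here. There were 26 fixed gene lists with 445 genes, of which 437 were found, and 65 pairs of list and class were measured with members of at least 20 UMIs. The percentile of a list is that of its median among the medians of 10000 random lists of equal size, drawn within 10 bins of expression. At the top 2.5% of such lists lay 16 pairs and at the bottom 2.5% lay 18. Lists reached such percentiles between the whole ears too. Examples are 100 for the Th1 effector list in T cell-like cells and 0 for MHC class II presentation in monocyte/macrophage-like cells. An extreme percentile alone therefore does not set niche and non-niche apart from libraries of one kind.

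A gene was taken to be at the level of free RNA in a class when, relative to the class that expresses it most, it stood at no more than 2 times the median level of the markers of that class. Where related classes express the same markers, this level also reflects shared expression, and the rule cannot tell that from free RNA. The share of UMIs in the top cell was computed for every named gene. Genes whose last 500 nucleotides share at least 25% of their 50-nucleotide words with another gene, by the GENCODE M21 transcripts, were held to share 3' sequence. Gene positions are those of GRCm38 (mm10). Values within clusters used clusters with at least 20 cells in both libraries.

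The steps were tested on simulated data, in which counts of both libraries were drawn from 1 common profile per class, with 200 genes set to differ. The sums were Poisson draws, the model that the intervals assume, without variation between cells. The rates below therefore check the calculation and leave out that variation, which could let more unchanged genes pass. Of genes set to differ 3-fold, 90.8% in neutrophil-like cells and 100% in the other classes passed the size in the right direction, and of genes set to differ 1.5-fold at most 4.62% did. Of unchanged genes, 118 of 4922 passed in neutrophil-like cells, 3 of 7526 in fibroblast-like cells and none in the other classes. Intervals held the true ratio for 95.0% to 96.6% of genes, at most 1 of 20 unchanged lists fell outside the middle 95% of random lists, and 20 of 20 lists shifted by 0.5 lay above it. All 100 of 100 planted copies of a 3' end were found and 0 of 100 genes without a copy were called.

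The filters, the clustering settings, the gene lists, the class markers, the naming rule, the size and the alternatives to them were fixed before the data were examined. The rules for free RNA, shared 3' sequence and values within clusters were set after the data were seen, and the runs that leave out the shallow neutrophil cluster and list members at the level of free RNA were added then too. Software was Python 3.11.15, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.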

Results

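Single-cell transcriptomes were made from ear skin of REX3 mice, a strain that carries fluorescent reporters for ligands of the chemokine receptor Cxcr3. The mice sampled by tissue punch had been immunized with ovalbumin in complete Freund's adjuvant and had received OT-II Th1 cells, CD4 T helper cells whose receptor recognises ovalbumin. On day 5, intravital imaging located clusters of CXCL10-positive cells around blood vessels, and 2 mm punches were taken from such a region (niche) and from a region of the inflamed ear without them (non-niche). Each region gave 1 library, and 2 further libraries came from whole ears, for which the labels do not say whether they were immunized. The niche library held 4181 barcodes and 27430272 unique molecular identifiers (UMIs), the non-niche library 4458 barcodes and 26816342, and the whole ears 9320 barcodes with 62166400 and 4134 barcodes with 34184120. After filtering, 3606, 3663, 8198 and 3541 cells remained, with a median of 4183.5, 2888, 5113 and 6959 UMIs per cell. With 1 library per region no difference between niche and non-niche has a replicate check, and none was tested. Intervals in brackets are 95% and cover counting error only. The difference between the whole ears, in the same quantity, shows how far these 2 libraries of one kind lay apart.

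Because the niche was chosen by its CXCL10 signal, the level of Cxcl10 checks the labels and is no finding. Over all cells, Cxcl10 (ENSMUSG00000034855, mm10 chromosome 5, 92346638 to 92348889) reached 877 CPM (UMI counts scaled to a common total) [865, 889] in the niche library and 573 [563, 583] in the non-niche library, against 1280 and 1081 in the whole ears. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) reached 218 [213, 224] and 187 [181, 192] CPM. Its log2 ratio of 0.22 was no larger in size than the −0.23 between the whole ears. Per class, the log2 ratio of niche to non-niche for Cxcl10 was 1.76 in T cell-like (higher in 2 of 4 clusters), 0.77 in monocyte/macrophage-like, 0.75 in neutrophil-like and 0.67 in dendritic cell-like cells, and −0.38 in fibroblast-like cells. Between the whole ears the log2 ratio for Cxcl10 in these classes was, in the same order, −0.34, 0.38, 0.23, 1.11 and −0.36. Cxcl11 was not analysed here.

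The first comparison asked which cells made up the niche. Neutrophil-like cells filled most of the niche library: 2371 cells or 65.8% [64.2, 67.3], against 150 cells or 4.10% [3.48, 4.79] of the non-niche library, a 16.1-fold higher share [13.7, 18.8]. Without any classes, S100a8, a calcium-binding protein abundant in neutrophils, reached 7859 CPM over all cells of the niche library, 711 in the non-niche library and 4911 and 6013 in the whole ears. Monocyte/macrophage-like cells took similar shares of both, 18.5% [17.2, 19.8] and 17.5% [16.3, 18.8]. T cell-like cells took 3.63% [3.05, 4.30] of the niche library and 7.67% [6.83, 8.58] of the non-niche library, 2.11-fold lower in the niche, and dendritic cell-like cells took 2.88% [2.36, 3.48] and 4.23% [3.60, 4.93], 1.47-fold lower. Fibroblast-like cells, which build the dermal matrix, took 2.97% [2.44, 3.57] against 18.7%, 6.30-fold lower [5.17, 7.69], but their ratio over the non-leukocyte classes alone was 0.855. Leukocyte classes together held 92.0% [91.1, 92.9] of the niche library and 39.7% [38.2, 41.4] of the non-niche library.

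Among the smaller classes, the share in the niche library was 4.96-fold lower [3.21, 7.67] for NK and innate lymphoid cell-like cells and 10.4-fold lower [6.89, 15.6] for keratinocyte-like cells. For mast cell- and basophil-like cells together it was 5.85-fold lower [3.56, 9.62], but their clusters went opposite ways. Cluster 14, with Gata2 and Mcpt8 among its leading genes, took 0.444% of the niche library (16 cells) and 0.164% of the non-niche library (6 cells). Cluster 31, led by Mcpt4, Cma1 and Cpa3, took 0.0555% and 2.76%. The share in the niche library was also lower for blood endothelial-like cells (4.68-fold [2.89, 7.56]), lymphatic endothelial-like cells (6.96-fold [3.99, 12.2]), pericyte- and smooth muscle-like cells (6.52-fold [3.11, 13.7]), melanocyte-like cells (11.3-fold [4.08, 31.4]) and Schwann cell-like cells (1.88-fold [1.23, 2.87]). Some of these directions depended on the setting: over non-leukocyte classes alone the ratio of niche to non-niche share was 2.87 for Schwann cell-like and 1.15 for blood endothelial-like cells, and with classes called cell by cell it was 1.19 for melanocyte-like cells. The non-niche cells of these smaller classes were shallower. Their median was 1029 UMIs against 36579 in the niche for keratinocyte-like, 1399 against 19997 for pericyte- and smooth muscle-like and 1211 against 5334 for mast cell- and basophil-like cells. Skeletal muscle-like cells numbered 20 in each library, erythroid-like cells 16 and 25, and B cell-like cells 3 and 0. In the whole ears the mean share was 37.1% ± 3.79 (SD, n = 2) for neutrophil-like, 31.6% ± 5.84 for monocyte/macrophage-like, 13.5% ± 0.298 for T cell-like, 2.59% ± 0.344 for dendritic cell-like and 4.01% ± 0.284 for fibroblast-like cells. The neutrophil share of the niche library thus lay above and that of the non-niche library below both whole ears, which held 34.4% and 39.7%.

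Live cells were sorted without a gate on cell type, so shares also reflect how well each type survived digestion, and shares of 1 library sum to 100%. Over leukocyte classes alone the neutrophil ratio was 6.94, the T cell ratio 0.205, the dendritic cell ratio 0.295 and the monocyte/macrophage ratio 0.455. With classes called cell by cell, the dendritic cell ratio turned to 1.37. Clusters 3 and 18 were kept out of every class by a threshold set after seeing the data. Cluster 3 held 0.721% of the niche and 20.8% of the non-niche library, and cluster 18 held 0.471% and 2.70%.

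**Figure D1:**
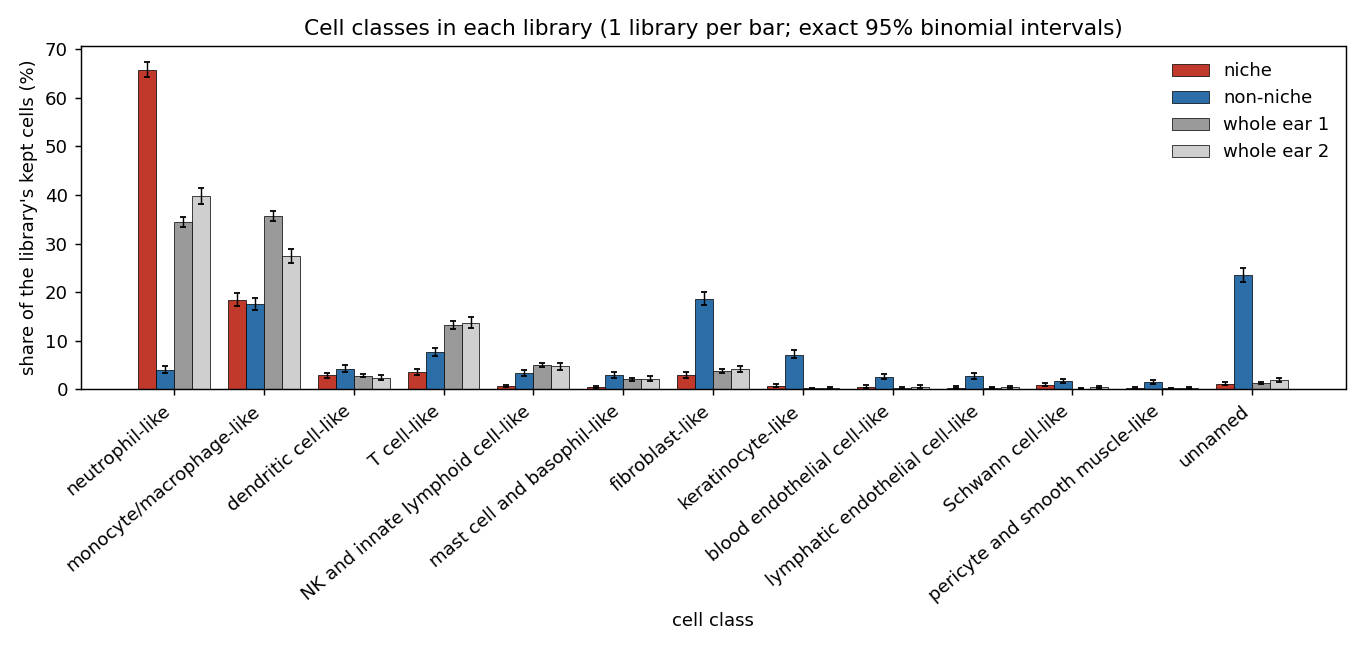
Share of the larger cell classes and of unnamed cells (percent of cells kept, vertical axis) in the niche, non-niche and both whole-ear libraries, with exact 95% binomial intervals as bars. Neutrophil-like cells took 65.8% of the niche library and 4.10% of the non-niche library, with the whole ears at 34.4% and 39.7%.

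The second comparison asked how the same class differed between niche and non-niche. In neutrophil-like cells of the niche library, transcripts of hypoxia-linked genes and of several inflammatory mediators were more abundant, and transcripts induced by type I interferon were less abundant. Of the glycolysis and hypoxia list, 20 of 23 measured members were higher in the niche library, with a median log2 ratio of 0.72 at percentile 100 of 10000 random lists matched on expression, against −0.04 between the whole ears. Within clusters this list was at 0.71 (cluster 15) and 0.57 (cluster 7), but at 0.16 (percentile 95.8) in cluster 10, which held most niche cells of the class. Ero1l, an oxidase of the endoplasmic reticulum (ENSMUSG00000021831, chromosome 14, 45283087 to 45318771), reached 679 against 141 CPM, 4.77-fold higher [3.74, 6.30]. P4ha1, a prolyl hydroxylase of collagen (log2 ratio 1.70), the mitophagy receptor Bnip3 (1.48) and the oxygen sensor Egln3 (1.35) went the same way. The chemokine gene Cxcl3 reached 2131 against 727 CPM, 2.93-fold higher [2.62, 3.29], Il1a was 3.59-fold higher [2.68, 5.05], the adhesion molecule Icam1 2.97-fold higher [2.29, 3.99] and Tnf 2.28-fold higher [1.91, 2.77].

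The type I interferon response list lay at a median log2 ratio of −1.15 in neutrophil-like cells, at percentile 0, with 26 of 26 members lower and 15 of them at least at a log2 ratio of −1. Ifit3, an interferon-induced antiviral gene (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), reached 90.0 against 440.0 CPM, a log2 ratio of −2.29 [−2.52, −2.05], and Ifit1 (−2.07) and Ifi27l2a (−1.91) lay near it. Between the whole ears the same list had a median of 0.21. The interferon-gamma response list was at 0.06, percentile 76.9, and at 0.35 under TMM scaling. Inflammatory cytokines were at 0.26 (15 of 21 members higher) and neutrophil maturation and activation genes at 0.19 (percentile 92.1; 0.09 to 1.10 within clusters). Dissociation stress genes were at 0.21 (percentile 96.1; −0.72 to 0.33 within clusters). All 12 measured genes encoded by mitochondria were lower, with a median of −2.04 that moved to −1.42 with cells of at most 5% mitochondrial UMIs and was −1.98 in cluster 15 and −1.48 in cluster 7 but only −0.17 (percentile 39.3) in cluster 10. The median mitochondrial share per cell was 0.204% in the niche and 0.515% in the non-niche library.

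In neutrophil-like cells, 749 of 5124 genes with at least 100 UMIs differed by at least 1 on the log2 scale, 372 higher and 377 lower in the niche library, against 31 between the whole ears. Under TMM scaling the split was 678 higher and 194 lower, and with the deeper sum thinned to the shallower one 135 genes passed. The non-niche sum came from 150 cells and 431845 UMIs, against 8031782 in the niche library. In data simulated for this class without variation between cells, 2.40% of unchanged genes passed the same size. Cluster 10 held 57.1% of the niche cells of this class, while cluster 15, the shallow neutrophil cluster, held 43.3% and cluster 7 held 31.3% of the non-niche cells. Highest by the naming rule were Tmc6, Slc32a1, B4galt7 and Aen, at least 3.69-, 2.64-, 2.13- and 1.90-fold higher against the floor of 3 counts in the non-niche class sum, and Serf1, 11.8-fold higher [4.07, 122] on 2 non-niche UMIs. Lowest were Crip1 (log2 ratio −3.86, moving to −0.53 without the shallow cluster) and the MHC class II genes H2-Aa (−3.98), Cd74 (−3.72), H2-Ab1 (−3.64) and H2-Eb1 (−3.29). Between 45.1% and 53.2% of the non-niche UMIs of these MHC class II genes came from 1 cell, all 4 were at the level of free RNA, and the last 3 changed direction without the shallow cluster, to 0.95, 0.39 and 0.39.

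Of the remaining lists in neutrophil-like cells, MHC class I presentation was at −0.19 (0.10 under TMM scaling), T cell costimulation and instructive ligands at −0.09 (0.19) and neutrophil- and monocyte-attracting chemokines at −0.02 (0.27), the last above 0 in 3 of 3 clusters (0.12 to 2.17). Chemokine receptors were at −1.33 over 6 members and at 0.03 without members at the level of free RNA. Cell cycle genes were at −0.98 over 5 members and at −0.12 without the shallow cluster.

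Monocyte/macrophage-like cells of the niche library carried more transcript of the nitric oxide synthase gene Nos2, the chemokine gene Cxcl3, inflammatory cytokines and hypoxia-linked genes, and less of type I interferon response genes. Nos2, the inducible nitric oxide synthase (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254), reached 760 against 125 CPM, 6.07-fold higher [5.61, 6.58], and was higher in each of the 4 clusters of the class, by 0.73 to 3.14 on the log2 scale. Cxcl3 (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600) reached 746 against 26.3 CPM, 28.3-fold higher [24.1, 33.8], and was higher in all 4 clusters, by 0.67 to 4.27 on the log2 scale, while the log2 ratio between the whole ears was −1.37. Ptges, a prostaglandin E synthase, reached 98.2 against 6.61 CPM, 14.7-fold higher [10.6, 21.3] but by 0.79 to 2.60 on the log2 scale within clusters, and Serpinb2, an inhibitor of plasminogen activators, was 35.6-fold higher [21.8, 67.7]. Mmp13, a collagenase, was 97.9-fold higher [38.9, 555] on 3 non-niche UMIs and Il12a, the p35 subunit of interleukin-12, 42.6-fold higher [11.2, 2533] on 1.

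The inflammatory cytokine list had a median log2 ratio of 0.61 in monocyte/macrophage-like cells (percentile 100, 16 of 20 members higher, 0.27 to 0.73 within clusters, −0.01 between the whole ears), with Il1a at 2.64, a value for which 68.9% of the non-niche UMIs came from 1 cell. The glycolysis and hypoxia list was at 0.51 (percentile 100, 21 of 24 members higher) and at 0.47 within cluster 13 but 0.05 to 0.15 within the other clusters, with Ero1l at 1.05, higher in 4 of 4 clusters, Eno1, which shares 3' sequence, at −1.01, and Egln3 at 2.82 but at 0.85 within the 1 cluster measured. The interferon-gamma response list was at 0.22 (percentile 100, 26 of 34 members higher), led by Nos2 and by Socs1, a feedback inhibitor of cytokine signalling, at 1.58 [1.43, 1.73]. Neutrophil- and monocyte-attracting chemokines went both ways around a median of 0.33, which was −0.41 within cluster 13: Ccl3 was 5.66-fold higher [4.96, 6.51], in 3 of 4 clusters, and Cxcl1 2.71-fold higher [2.22, 3.35], in 2 of 3, but Ccl9 was 2.76-fold lower [2.62, 2.92], in 4 of 4. All 28 members of the type I interferon response list were lower, with a median of −0.52 at percentile 0 against 0.38 between the whole ears, and Isg20 at −1.57. The MHC class II presentation list was at −0.59 (percentile 0.01, 10 of 11 members lower, −0.20 between the whole ears), with H2-Aa at −0.88, Cd74 at −0.66 and the lysosomal protease Lgmn at −1.31. Much of this went with the mix of clusters, since the list was at −0.12 and −0.10 within clusters 11 and 13, inside the range of random lists, and at −0.30 and −0.45 within clusters 12 and 17. H2-Aa and Cd74 stood at 20.3% and 22.6% of their level in dendritic cell-like cells, close to the 19.9% of dendritic cell markers. Markers that both classes express can give that level too. H2-Aa was among the leading genes of cluster 13, so free RNA and expression cannot be told apart here. Without members at the level of free RNA, the MHC class II presentation list was at −0.21 (percentile 14.5) over 4 members. Neutrophil markers stood at only 1.97% of their level in neutrophil-like cells in the niche cells of this class, although neutrophil-like cells filled most of that library.

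Of the tissue-repair macrophage list, 8 of 23 members were at or under −1 and 2 at or above 1, around a median of −0.30 (percentile 1.42; 0.19 within cluster 12). Folr2, a folate receptor of resident macrophages, was 7.55-fold lower [4.99, 12.2] (log2 ratio −1.73 within the 1 cluster measured) and Igfbp7 7.75-fold lower [4.67, 14.3]. Lyz1 was 38.4-fold lower [19.5, 104], at 37.7% of its level in dendritic cell-like cells against 19.9% for the markers of that class, so free RNA or expression shared with that class could give part of it. Gstp1 was 12.1-fold lower but shares 3' sequence with another gene, and 96.7% of the Retnla UMIs of the non-niche library came from 1 cell. MHC class I presentation was at −0.20, dissociation stress at −0.20, chemokine receptors at 0.07, mitochondrially encoded genes at 0.07 and cell cycle at −0.42. T cell costimulation and instructive ligands were at 0.08 (percentile 99.3; 0.14 between the whole ears), but below 0 in 3 of 4 clusters. Lymphocyte-attracting chemokines were at −0.76 over 5 members and turned to 0.77 with cells of at least 500 detected genes. In all, 335 of 7512 genes passed the size, 169 higher and 166 lower, against 40 between the whole ears, and the split was 247 to 105 under TMM scaling. Macrophage-like cluster 17, led by Nos2 and Arg1, held 45.9% of the niche cells of this class and macrophage-like cluster 13, led by C1qb, held 55.8% of the non-niche cells. Median depth was 13538.5 UMIs per cell in the niche and 7833.5 in the non-niche library.

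**Figure D2:**
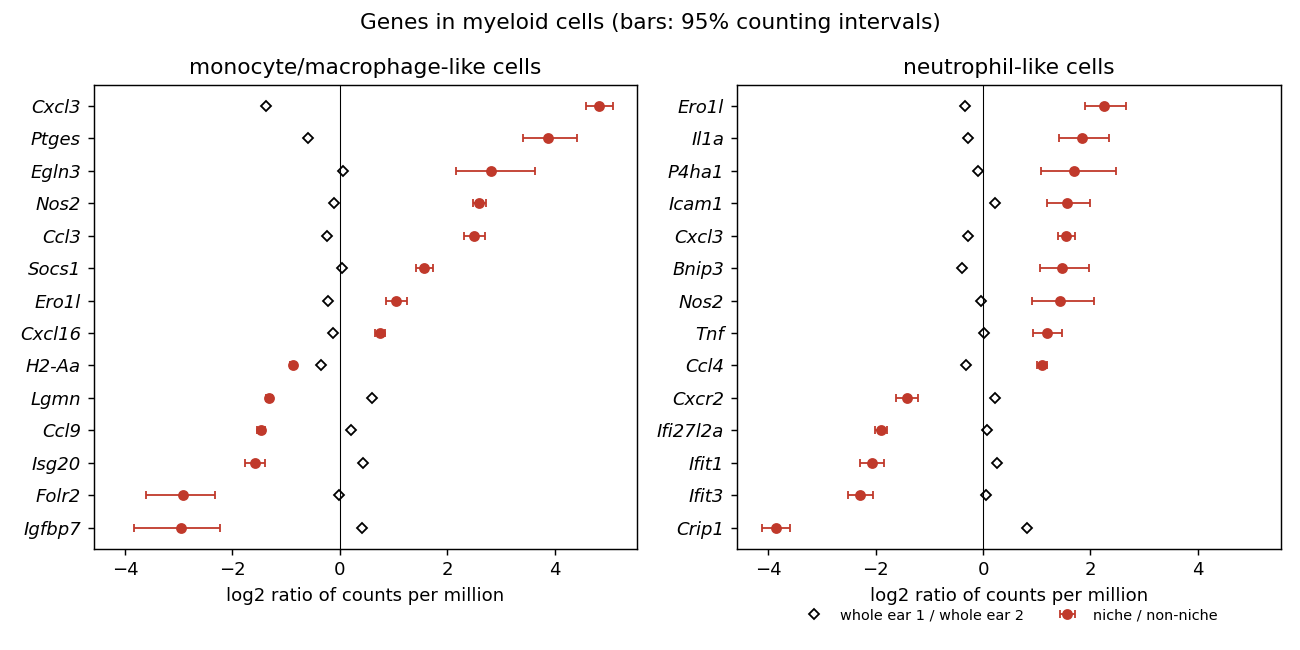
Log2 ratio of CPM, niche over non-niche (horizontal axis), for named genes in neutrophil-like and monocyte/macrophage-like cells, with exact 95% intervals of counting error as bars and the ratio between the whole ears as open diamonds. Cxcl3, Nos2 and Ero1l lie above 0 in both classes.

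Dendritic cell-like cells, all in 1 cluster with Ccr7 and Fscn1 among its leading genes, showed the largest ratio of niche to non-niche in interferon-gamma response genes of the 5 classes compared. The median log2 ratio of that list was 0.98 (percentile 100), with 32 of 33 members higher and 15 of them at least at 1, against 0.16 between the whole ears. Iigp1, an interferon-inducible GTPase (ENSMUSG00000054072, chromosome 18, 60376027 to 60392634), reached 276 against 44.9 CPM, 6.12-fold higher [4.77, 8.05], Serpina3g was 2.91-fold higher [2.02, 4.34] and Cxcl9 2.30-fold higher [2.01, 2.63]. The type I interferon response list was higher as well, at 0.52 (percentile 100, 24 of 27 members), with the antiviral genes Ifit2 and Rsad2 2.72-fold [2.06, 3.66] and 2.40-fold higher [1.86, 3.16], but the whole ears differed by 0.67 in the same list.

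Glycolysis and hypoxia genes were higher in dendritic cell-like cells too, at 0.48 (percentile 100, 17 of 22 members, 0.37 between the whole ears), with the vascular growth factor Vegfa at 1.46, the aldolase Aldoa at 1.12 and Bnip3 at 1.30, while the enolase Eno1, which shares 3' sequence with another gene, was at −1.55. Ptgs2, the inducible cyclooxygenase, was 3.35-fold higher [2.83, 3.99] (log2 ratio between the whole ears 1.11), Pdcd1lg2, the PD-L2 ligand, was at 1.21, and Ccr7, the receptor that guides dendritic cells to lymph nodes, was at 0.60. Neutrophil- and monocyte-attracting chemokines had a median of −1.12 over 9 members (percentile 0; −0.37 with at least 100 UMIs), with Ccl2 at −1.90, Ccl6 at −1.41 and Ccl7 17.6-fold lower [6.66, 101] on 3 niche UMIs, while Cxcl3 was at 5.99 with 52.6% of its niche UMIs in 1 cell. Inflammatory cytokines were at 0.21 (percentile 98.9) with 4 members at least at 1 and 4 at or under −1, among them Il6 at −2.72.

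MHC class II presentation was at −0.04 in dendritic cell-like cells (0.04 under TMM scaling), MHC class I presentation at 0.13, lymphocyte-attracting chemokines at −0.20, chemokine receptors at 0.30, cell cycle at −0.38, dissociation stress at 0.05 and mitochondrially encoded genes at −0.27. T cell costimulation and instructive ligands were at −0.25, and at 0.44 with at least 100 UMIs. By the naming rule Nos2 was at least 35.3-fold higher, with 45.5% of its niche UMIs in 1 cell, and Inhba 31.0-fold higher [12.0, 177] on 3 non-niche UMIs. Both stood at the level of free RNA, a level that expression shared with monocyte/macrophage-like cells can also give. Mfge8 (63.2% of niche UMIs in 1 cell) and Slpi (35.6%, at the level of free RNA) were 18.5- and 18.1-fold higher. Timp2, an inhibitor of metalloproteinases, was 4.35-fold lower [2.71, 7.60], the metallothionein Mt2 4.24-fold lower [3.49, 5.23] and the tetraspanin Cd81 6.82-fold lower [3.93, 13.7]. Il12b was at −2.28, but 88.0% of its non-niche UMIs came from 1 cell and without the top cells it was at −0.49, and 94.4% of the Mucl1 UMIs came from 1 cell. In all, 173 of 3747 genes passed the size, 101 higher and 72 lower, against 101 genes between the whole ears.

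T cell-like cells of the niche library carried more transcript of interferon-gamma response genes and far less of type I interferon response genes. The class mixes lineages, since Trdc, a marker of gamma-delta T cells, was among the leading genes of clusters 16 and 28. These clusters held 17.6% and 24.4% of the niche cells of the class and 21.4% and 7.83% of the non-niche cells. Values of the class therefore do not describe CD4 T cells alone. The interferon-gamma response list had a median log2 ratio of 0.39 (percentile 100, 25 of 28 members higher), although the whole ears differed by 0.41 in it. Within clusters it was at 0.09 (percentile 91.3) in cluster 6, 0.24 in cluster 5, 0.94 in cluster 16 and 1.49 in cluster 28. Gbp2, a guanylate-binding protein (chromosome 3, 142620602 to 142638008), reached 220 against 109 CPM, 2.02-fold higher [1.68, 2.42], and was higher in each of the 4 clusters of the class. Socs1 was at 1.01 and Serpina3g at 1.14. Of the type I interferon response list, 23 of 24 members were lower and 14 of them at or under −1, with a median of −1.31 (percentile 0), and the whole ears differed by 0.83. Within clusters the median was −1.99 and −1.03 in clusters 6 and 5, −0.27 in cluster 16 and 1.14 over 6 members in cluster 28. Ifit3 reached 4.08 against 75.7 CPM, a log2 ratio of −4.08 [−5.86, −2.96], Ifit1 was at −2.22 and Isg20 at −1.78.

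The Th1 effector list of T cell-like cells was at −0.13 (percentile 12.4; −0.40 to 0.25 within clusters). Regulatory T cell genes were at −0.08 (−0.71 within cluster 5, 0.33 within cluster 16), T cell receptor activation at −0.11 (0.65 within cluster 16, −0.54 within cluster 28) and chemokine receptors at −0.11, the last above 0 in 3 of 3 clusters (0.07 to 0.50). Ifng (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), the defining cytokine of Th1 cells, reached 49.8 against 144 CPM, but 74.0% of its non-niche UMIs came from 1 cell, and without the top cell of each library it was at 36.2 against 38.4 CPM, a log2 ratio of −0.08 [−0.65, 0.47]. Naive and central-memory T cell genes were at −0.54 (percentile 0.06), with the transcription factor Tcf7 at −0.63 and lower in 4 of 4 clusters. Within clusters this list was at −0.31 (cluster 5), −0.56 (cluster 16) and 0.29 (percentile 99.0, cluster 6). Gata3 was at −1.26 [−1.59, −0.95], lower in 3 of 3 clusters measured. The type 17 lymphocyte list was at −0.43 (percentile 0.27; 0.21 within cluster 28), yet Il17a was at 1.83 and Il17f at 1.51, with 33.3% and 41.6% of their niche UMIs, and 39.6% and 49.3% of their non-niche UMIs, in 1 cell.

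MHC class I presentation was at 0.01 in T cell-like cells, glycolysis and hypoxia at 0.13 (percentile 96.2), cell cycle at −0.03 (0.02 under TMM scaling; 3.86 within cluster 28, −0.67 within cluster 5), dissociation stress at −0.02 (−0.41 and −0.46 within clusters 5 and 6) and mitochondrially encoded genes at −0.29. By the naming rule the actin-binding gene Avil was 5.55-fold higher [4.27, 7.35] but only at a log2 ratio of 0.86 within cluster 28, the 1 cluster measured, and Ccl3 6.92-fold higher with 65.2% of its non-niche UMIs in 1 cell, while Wdr89 (2.55), Bloc1s1 (2.35), Hist1h2ap (−4.17), Gstp1 (−2.96) and Il22 share 3' sequence with other genes. Slpi (72.9% of niche UMIs), Il22 (87.7% of non-niche UMIs) and Apoe (65.5%) rested mostly on 1 cell, and so did the list member Csf2 (98.0% of niche UMIs). In all, 149 of 4394 genes passed the size, 65 higher and 84 lower, against 81 between the whole ears. Cluster 6 held 38.1% of the non-niche and 28.2% of the niche cells of this class, and cluster 28, with Cd3g and Trdc among its leading genes, held 7.83% and 24.4%.

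Fibroblast-like cells of the niche library carried less transcript of extracellular matrix genes and more of interferon-gamma response and dissociation stress genes. Of the extracellular matrix list, 25 of 26 members were lower, with a median log2 ratio of −0.34 (percentile 0.01), against 0.06 between the whole ears and −0.33 to −0.11 within clusters. The matricellular gene Thbs1 was 2.24-fold lower [2.12, 2.37] and lower in 3 of 3 clusters, Postn was 2.10-fold lower [2.01, 2.19], though only in 2 of 3 clusters and at a log2 ratio of no less than −0.72 within them, and Thbs2 1.98-fold lower [1.69, 2.33], while Col15a1 at −1.38 moved to −0.23 with cells of at least 500 detected genes. The interferon-gamma response list was at 0.45 (percentile 100, 23 of 29 members higher), with the immunoproteasome subunit Psmb9 at 1.00. The dissociation stress list, which tissue digestion can raise, was at 0.47 (percentile 100; 0.26 to 0.67 within clusters) with 2 of 24 members at least at 1, Atf3 (2.40-fold higher [2.26, 2.55]) and Fos (2.13-fold [2.06, 2.20]). Lymphocyte-attracting chemokines were at −0.94 over 6 members (percentile 0.07; −1.76 with cells of at least 500 detected genes), with Cxcl12 at −0.69 and Ccl19, which shares 3' sequence with other genes, at −2.54.

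Several other genes of fibroblast-like cells followed neutrophil RNA. Neutrophil markers stood at a median of 4.96% of their level in neutrophil-like cells in niche fibroblast-like cells and at 0.423% in non-niche ones. In the niche library they stood at only 1.08% in T cell-like, 0.99% in dendritic cell-like and 1.97% in monocyte/macrophage-like cells. Free RNA alone may thus not give the level in fibroblast-like cells, and its source was not tested. Hcar2, Upp1, Slc7a11, Cxcl3 and Fcer1g were the highest by the naming rule, at log2 ratios of 4.55 to 3.04. All were at the level of free RNA by its rule, as were Cd14 and Lcn2 in the inflammatory cytokine and inflammatory fibroblast lists. The inflammatory cytokine list was at 0.83 (percentile 100, 14 of 18 members higher) and at 0.29 without such members, with −0.65 within cluster 1, and the inflammatory fibroblast list at −0.29 with 6 members at least at 1 and 6 at or under −1. Within cluster 21 the inflammatory fibroblast list went the other way, at 0.94 (percentile 100), against −0.26 in cluster 0. Ccl11, the chemokine eotaxin (ENSMUSG00000020676, chromosome 11, 82057823 to 82062955), was at −3.73, at 4.47% of its level in pericyte- and smooth muscle-like cells against 2.25% for the markers of that class, and moved to −0.38 with cells of at least 500 detected genes. Hmcn2 (38.6-fold lower [10.3, 2292]) and Plac9b, which shares 3' sequence, had 1 niche UMI each, Slurp1 had 3, and all Otor UMIs came from 1 cell.

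Type I interferon response was at 0.03 in fibroblast-like cells (−0.03 under TMM scaling; −0.53 to 0.36 within clusters) and MHC class I presentation at 0.04 (−0.01). MHC class II presentation was at −0.67, neutrophil- and monocyte-attracting chemokines at 0.35, glycolysis and hypoxia at 0.18 and mitochondrially encoded genes at −0.07. Too few MHC class II members stood above the level of free RNA to measure that list without the others. Its lower median may therefore not reflect expression by fibroblast-like cells. Cell cycle genes were at 1.59, less than the 2.46 between the whole ears, and at 0.31 with at least 100 UMIs. In all, 368 of 7722 genes passed the size, 177 higher and 191 lower, against 113 between the whole ears. Clusters 0 and 21 held most of the class in both libraries.

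**Figure D3:**
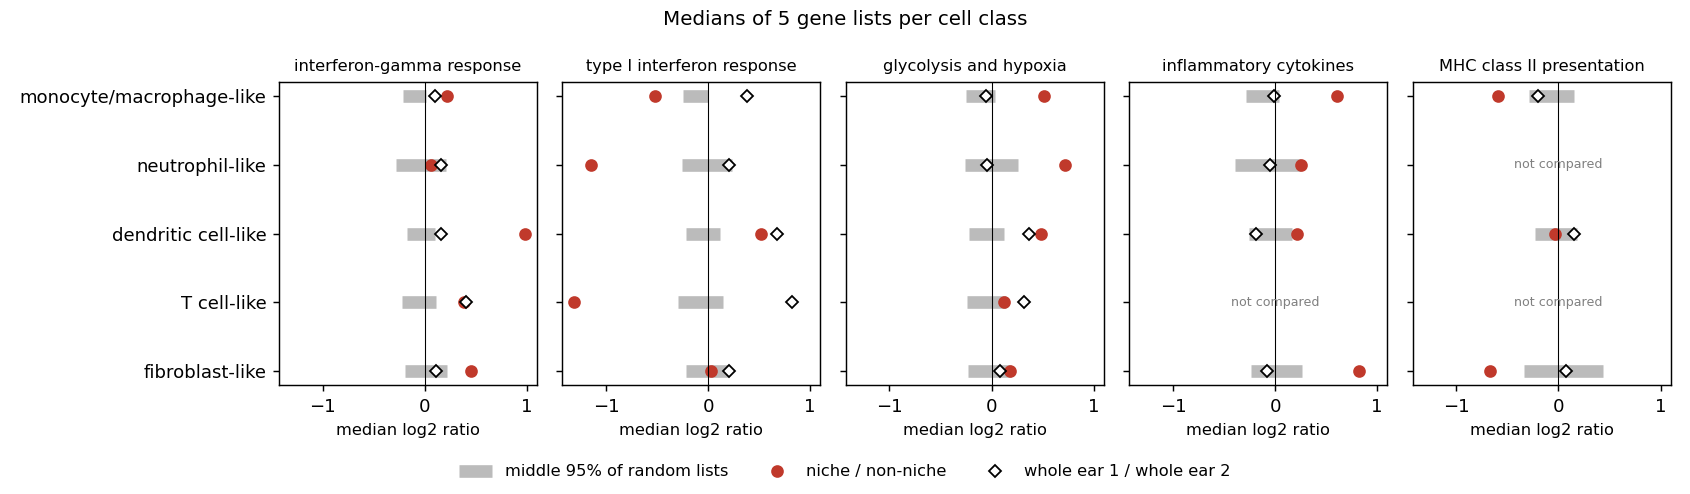
Median log2 ratio, niche over non-niche, of 5 gene lists (panels) in each cell class, with the middle 95% of random lists as grey bars and the ratio between the whole ears as open diamonds. The type I interferon response list lies below 0 in T cell-, neutrophil- and monocyte/macrophage-like cells and above 0 in dendritic cell-like cells, and the interferon-gamma response list lies at or above 0.06 in all 5 classes.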

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

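The tests on the neutrophil share and on cluster 3 were chosen only after the result was seen.

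Neutrophil-like cells took 65.8% of the niche library and 4.10% of the non-niche library. Had every barcode that the filters left out of the non-niche library and every unnamed cell in it been a neutrophil, its share would be 40.5%, under the lower bound of 55.2% for the lowest possible niche share. Neutrophils lost to these filters thus cannot account for all of the difference. They could account for part of it, so its size is not bounded closely, and droplets lost before the barcodes were called were not counted. Fewer non-leukocyte cells recovered from the niche punch would leave the shares among leukocytes alike, but the ratio of neutrophil shares among leukocytes was 6.94. Poor recovery of leukocytes that reside in the tissue would raise that ratio too, so it stays open. More blood in the niche punch stays open: the ratio of haemoglobin CPM was 1.02, but haemoglobin stood at 109 and 9070 CPM in whole ears with similar neutrophil shares and so does not track neutrophils. Whether any pair of punches would differ as much stays open, since the whole ears, which differed 1.16-fold, are not punches.

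Cluster 3 held 20.8% of the non-niche library [19.5, 22.1], against 0.721% of the niche library and 0.488% and 1.10% of the whole ears, and it belongs to no class. Its non-niche cells were shallow, with a median of 1025 UMIs, and haemoglobin genes took 7.32% and fibroblast markers 5.05% of their UMIs, against 41.9% and 2.97% in its niche cells. Damaged fibroblasts that took up free haemoglobin RNA could give such cells, and so could erythroid cells with free fibroblast RNA. If they were fibroblasts, the fibroblast share of the non-niche library would be higher still than 18.7%, and the direction of that difference would stay.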

How the results depend on the processing

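The tests without the shallow neutrophil cluster and without members at the level of free RNA were chosen only after the result was seen. No paired analysis was possible because each region gave 1 library and the groups share only the replicate number 1. Of log2 ratios under other settings, 1574 stayed, 238 moved and 27 turned; of list medians 605 stayed, 13 moved and 3 turned; of ratios of class shares 91 stayed, 48 moved and 4 turned; of gene counts 39 stayed and 17 moved, and all 32 whole-ear mean shares stayed. A value counts as turned only where its direction changed and the reported value stood apart from no difference, by its interval or, for a list, by a percentile in the outer 5% of random lists. Other changes of direction count as stayed or moved: 19 log2 ratios, 54 list medians and 8 ratios of class shares. A value stayed if it lay inside the reported interval or, for a list, no further from the reported median than 0.5 times the width of its interval, and a gene count stayed if it changed by no more than 1.5-fold. For the ratio of class shares, niche to non-niche, neutrophil values moved from 16.1 to 22.8 (at least 500 detected genes), 19.0 (at most 5% mitochondrial UMIs), 23.3 (doublets kept), 22.99 (resolution 2), 22.6 (resolution 0.5), 24.0 (response lists kept in the clustering genes), 22.4 (niche and non-niche libraries alone), 21.8 (cells thinned), 20.1 (classes per cell), 26.6 (without the shallow cluster) and 6.94 (leukocytes only). For the ratio of class shares, niche to non-niche, fibroblast values moved to 0.0969 (at least 500 genes), 0.108 (doublets kept), 0.0995 and 0.201 (resolution 2 and 0.5), 0.108 (response lists kept), 0.105 (niche and non-niche alone), 0.0913 (thinned), 0.113 (per cell) and 0.855 (non-leukocyte classes only). With the ratio of class shares, niche to non-niche, monocyte/macrophage values moved across 1, from 1.05 to 0.814 (niche and non-niche alone), 0.872 (thinned) and 0.455 (leukocytes only). With the ratio of class shares, niche to non-niche, T cell values moved to 0.352 (thinned) and 0.205 (leukocytes only), and dendritic cell values to 0.480 (response lists kept), 0.295 (leukocytes only) and, in the other direction, 1.37 (per cell). Over non-leukocyte classes the ratio of class shares, niche to non-niche, erythroid, also moved across 1, to 3.50, from a value whose interval held 1. Also turned were the ratios of Schwann cell shares (2.87) and blood endothelial shares (1.15) over non-leukocyte classes and of melanocyte shares (1.19) per cell. The number of genes past the size rule, T cell class, moved to 716 (at least 20 UMIs), 3502 (no minimum) and 654 (absolute log2 ratio of at least 0.58). In the same order the number of genes past the size rule, dendritic cell class, was 688, 4484 and 571, the number of genes past the size rule, fibroblast class, 1194, 3819 and 1414 (235 with the deeper sum thinned), the number of genes past the size rule, monocyte/macrophage class, 876, 3857 and 1183, and the number of genes past the size rule, neutrophil class, 2143, 7739 and 1853 (135 thinned). The median log2 ratio of lymphocyte-attracting chemokines in monocyte/macrophage-like cells turned to 0.77 (at least 500 genes) and 0.82 (response lists kept). That of chemokine receptors in neutrophil-like cells turned to 0.0273 (free RNA left out), and that of interferon-gamma response there moved to 0.35 (TMM). In neutrophil-like cells, log2 ratios turned in order of at least 500 genes, doublets kept, resolution 2, response lists kept and no shallow cluster to 0.61, 0.55, 0.57, 0.68 and 0.95 for Cd74 and to 0.27, 0.35, 0.22, 0.21 and 0.39 for H2-Eb1. In the same order the log2 ratio, H2-Ab1, neutrophil-like cells, turned to 0.20, 0.0911, 0.11, 0.18 and 0.39. Hspa8 turned there to 0.23, 0.16, 0.15 and 0.25 and Klf4 to 0.95, 0.80, 0.80 and 0.96 (at least 500 genes, resolution 2, response lists kept, no shallow cluster). Ccl17 turned in monocyte/macrophage-like cells to 0.96 (at least 500 genes) and 0.88 (response lists kept), and Il22 turned in T cell-like cells to 2.89 (doublets kept). Under that setting the log2 ratio, Ifng, dendritic cell-like cells, turned to 0.0173. Most of these settings change which cells a class holds, and the cause was not tested.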

Other observations

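The tests on the type I interferon response list by cluster and between the whole ears, and the levels of ligands in small classes, were chosen only after the result was seen.

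The ligands that mark the niche were abundant in small classes of the tissue. In Schwann cell-like cells, the glia of skin nerves, Cxcl10 reached 7984 CPM [7606, 8375] in 32 niche cells and 299 [228, 385] in 61 non-niche cells, against 2936 and 4073 in the whole ears. In blood endothelial-like cells it reached 3073 [2853, 3305] in 20 niche cells and 1320 [1234, 1411] in 95 non-niche cells, but 2830 and 35.5 in the whole ears. Over all cells Ifng, which induces both ligands, was at a log2 ratio of −1.66 [−1.90, −1.43]. Of its 635 non-niche UMIs, 300 lay in T cell-like cells, and 1 cell held most of those. T cell-like and NK and innate lymphoid cell-like cells also took smaller shares of the niche library. The 24 NK and innate lymphoid cell-like cells of the niche library held 67.2% of its Ifng UMIs at 588 CPM [493, 696], against 379 [337, 425] in 121 non-niche cells and 832 and 936 in the whole ears. Few cells stand behind these values, and they may rest on the cells that survived digestion. Median depth was also lower in the non-niche library, at 1613 UMIs against 5746 in Schwann cell-like and 2687 against 9731.5 in blood endothelial-like cells.

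The type I interferon response list was lower in the niche library in T cell-, neutrophil- and monocyte/macrophage-like cells. In neutrophil-like cells a different mix of the 3 clusters measured cannot alone account for this, since the highest median within them was −0.69. That of cluster 15 (−0.71, percentile 7.98) lay inside the range of random lists, however. Clusters 8 and 9, with 2 non-niche cells each, were not measured. The response lists were left out of the clustering genes, so a mix of cells within a cluster was not tested. A mix of clusters could account for part of the lower medians in monocyte/macrophage-like cells (highest −0.20) and in T cell-like cells. Among the latter, cluster 28, with Cd3g and Trdc among its leading genes, stood at 1.14 with 6 members. Reads shared between near-identical genes of the list cannot account for the lower medians, since without such members they were −0.50 or lower. A difference between any libraries of one kind stays open: the whole ears differed by up to 0.83. Less type I interferon in the niche is a possible reading for these 3 classes only, since the list was at 0.52 in dendritic cell-like and 0.03 in fibroblast-like cells.

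Some genes differed alike in all classes measured between niche and non-niche: 15 higher, among them Wdr89 and Rnaset2b, and 10 lower, among them Gstp1, Rpl35 and H2-Q6. Of these 25 genes, 80.0% share 3' sequence with another gene, against 3.90% of all 7695 genes measured with an annotated 3' end, a pattern in line with reads shared between near-identical copies of a gene and assigned differently in the niche library. Neutrophil RNA in every class of the niche library might add to it, since 40% of the higher ones were highest in neutrophil-like cells, Slpi and Cxcl3 among them, but Nos2 was highest in monocyte/macrophage-like cells. Such genes numbered 44 and 35 between niche and the whole ears (61.4% and 71.4% sharing), 20 and 15 between non-niche and the whole ears (35.0% and 13.3%) and 5 between the whole ears (80.0%), so the number of such genes was largest in comparisons with the niche library, while their sharing was as high between the whole ears. Log2 ratios of Wdr89, Gstp1 and other genes with copies are therefore uncertain as biology.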
